A study of Homo sapiens with 6 samples.

How the data were processed

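CircRNA levels were measured in H9 cells, a human T-cell line, in 6 flasks: 3 grown in 0% and 3 in 50% smoke-exposed medium for 24 h, per the labels' protocols. Total RNA was treated with RNase R, reverse transcribed with random primers, amplified by T7 polymerase and labelled with Cy3, per the labels' protocols. Because enrichment by RNase R and linear amplification both act before hybridisation, differences in either between samples could enter every probe of an array. Groups and replicate numbers were taken from the sample titles. The labels describe 6 separate flasks and name no repeat of the experiment, so the p-values measure the spread between these flasks.

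The deposited scanner tables hold 1 spot per row with its intensity on a linear scale, in 1 colour. Per the file headers, the processed intensity had been background-subtracted and detrended within each array by Agilent Feature Extraction 11.0.1.1 and had not been normalised between arrays. The submitters' processing notes also name limma, with no version or setting. The authors' deposited table of log2 values covers the 13617 circRNA probes. Its medians per array lay between 6.95 and 7.00 and its maxima were all 17.1, as a quantile normalisation leaves them, and its rank correlation with the processed intensity of the same array was 0.997 to 0.999. Its rank correlation with the median spot intensity was slightly higher on every array (0.9984 to 0.9998). The scale and the direction of that table were settled by these comparisons, and its input signal and background correction stay unknown. The array design's header names a human genome build that differs from the assembly of the reference table, so no coordinates are given.

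Each array held 15603 spots, 536 of them control spots, which were left out. Spots marked as outliers (521 over all arrays, 30 of them circRNA spots) were left out, spots of 1 probe were averaged, and no spot was saturated. This left 13762 probes: 13617 circRNA probes with 1 spot each, and 70 mRNA, 15 circRNA control and 60 negative probes with 10 spots each. The 70 mRNA probes carry RefSeq transcript accessions, all 70 of which matched a gene symbol in the GRCh38.p14 reference table. The circRNA probes carry only identifiers of the array's maker, which neither the files nor the reference table pairs with a circRNA name, a class or a host gene. Whether an mRNA probe also detects a circRNA of the same gene was not tested.

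The log2 processed intensity minus the array's 75th percentile was the level of a probe. The percentile was taken over all 13762 probes, since 79.1% of them were well above background on all 6 arrays. A probe was tested where it was well above background (in more than 0.5 of its spots) on every array of at least 1 group, which kept 13126 circRNA probes, left out 491, and kept 64 mRNA and 15 circRNA control probes. Of the tested probes, 2301 circRNA and 23 mRNA probes met this in smoke alone, and 1 and 0 in control alone. The 6 mRNA probes not tested were those of ZZZ3, PLA2G4A, POGLUT2, DSCC1, RPAP3 and CD69. Signal over background bounds what the arrays can show: between 8 and 54 of the 60 negative probes were themselves marked well above background on an array. Smoke was compared with control in limma 3.58.1 under R 4.3.3 (linear model and empirical Bayes, two-sided), with Benjamini-Hochberg adjustment within the circRNA, mRNA and circRNA control probes separately and a threshold of 0.05. A fold of at least 1.5 with an unadjusted p under 0.05 gave a second, looser count. Measures of whole arrays were compared by exact permutation tests, adjusted over the 13 measures. Figures were drawn with matplotlib 3.10.9.

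The comparison, the alternatives, 15 gene lists and the rule for naming probes were fixed before the data were examined. The rule named the 10 probes with the largest change per direction among those called, well above background on all 6 arrays and without overlap between groups. With fewer than 5 called in a direction, it took the 10 with the smallest unadjusted p that met the other conditions. It also named up to 3 called probes per direction below background in 1 group, up to 3 probes per gene list by p, a list of known circRNAs, and up to 5 host genes with the most called circRNAs. Since the circRNA probes have no gene names here, at most 2 identifiers per direction are printed, the rule was applied to the mRNA probes as well, and 0 of the known circRNAs could be matched by identifier. List tests with camera needed at least 5 tested probes in a list, which none of the 15 lists reached, so none was run; tests by circRNA class were not run either. 1 item of these lists is not reported here. EIF3D and RPS18 lie outside the rule and were named after their values were seen.

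The fit was tested on simulated data for the comparison of smoke with control. In 20 runs over 13126 independent probes, 200 probes were changed by 2-fold or 4-fold. The spread of each probe was limma's estimate, which shares variance between probes, not the spread measured for that probe. At an adjusted p under 0.05, 3.2% of the 2-fold and 72.3% of the 4-fold changes were called, and 6.44% of the calls were false. For camera with an estimated correlation, over 64 mRNA probes and lists of 10 independent members, 97% of lists shifted 2-fold and 1.5% of unshifted lists were called. The real lists tested this way had estimated correlations of 0.497 and 0.458 among their members, so these rates may not hold for them.

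The alternatives covered the scaling (quantile, median, another probe set for the percentile, none), the background correction, the authors' deposited log2 values, the filter on dim probes, the replicate number as a block, the variance model, the threshold, and each array left out in turn. The normexp correction was run with an offset of 50 on the median spot intensity and the median local background, since the deposited tables analysed here have no mean spot intensity. All 6 arrays come from 1 slide, so a slide block could not be fitted. Alternatives chosen after seeing the data were a background correction from the negative probes (offset 16), the mean log2 signal of the negative or of the mRNA probes as a covariate, the row of the array on the slide (4 arrays in row 1, 2 in row 2; read from a header field and assumed from the maker's usual convention), a filter at the 95th percentile of the negative probes, and leaving out control 3 and smoke 2.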

Results

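The comparison asked whether exposure to cigarette smoke alters circular RNA (circRNA) levels in human T cells. H9, an established human lymphocytic T-cell line, was cultured for 24 h in medium holding 50% smoke-conditioned medium (smoke, n = 3 flasks) or 0% (control, n = 3 flasks). CircRNAs are covalently closed products of back-splicing, and their lack of free ends makes them resistant to the exonuclease RNase R. RNA treated with RNase R was hybridised to 6 arrays in 1 colour, each with 13617 circRNA probes, 70 probes for mRNAs of named genes, 15 circRNA control probes and 60 negative probes. The circRNA probes well above background numbered 12869, 10830 and 13577 on controls 1, 2 and 3, and 13540, 13603 and 13130 on smoke arrays 1, 2 and 3. The group means were 12425 ± 1426 (SD, n = 3) in control and 13424 ± 257 (SD, n = 3) in smoke, which did not differ beyond the spread between arrays (exact permutation test, two-sided, p = 0.3; adjusted p = 0.488). The difference of 999 probes fell to 201 without control 2. The 75th percentile of signal was 205 ± 62.6 units in control and 259 ± 23.8 units in smoke (SD, n = 3; exact permutation p = 0.3), a difference of 53.9 that was 29.2 without control 2 and 89.1 without control 3. The share of circRNA probes brighter than the 95th percentile of the negative probes ranged from 42.6% on control 3 to 64.7% on smoke 3. The number of such probes was higher on all 3 smoke arrays than on every control array, with means of 8605 ± 320 and 7390 ± 1379 (SD, n = 3; exact permutation p = 0.1, adjusted p = 0.488 over 13 array measures). The nearest arrays of the 2 groups differed little, with 8236 on smoke 1 and 8230 on control 1, and the difference of 1215 between the means fell to 419.5 without control 3. With 3 arrays per group, 0.1 is the smallest p that this exact test can give, and the number of arrays limits the precision of every value given here.

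**Figure D1:**
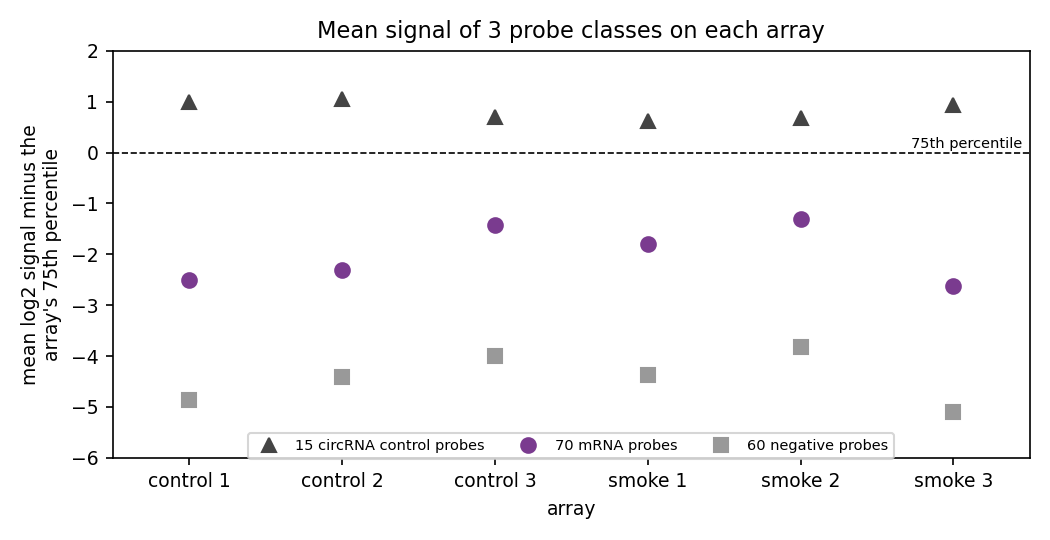
Mean log2 signal of the 70 mRNA probes (circles), 15 circRNA control probes (triangles) and 60 negative probes (squares) on each of the 6 arrays, as the difference from the array's 75th percentile (dashed line at 0). The mRNA probes lay between -2.63 on smoke 3 and -1.30 on smoke 2, with control 3 at -1.43, so arrays of both groups were found at the high and the low end.

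Of the circRNA probes well above background on all 6 arrays and without overlap between groups, ASCRP3009687 and ASCRP3012600 had the smallest p on the higher side, and ASCRP3007235 and ASCRP3008172 on the lower side. ASCRP3009687 was -1.86 ± 0.40 in control and 0.27 ± 0.34 in smoke (log2 relative to the 75th percentile, SD, n = 3), a difference of 2.13 on the log2 scale (SE 0.317), or 4.37-fold. ASCRP3012600 differed by 1.64 (SE 0.254), or 3.13-fold. ASCRP3007235 was 1.62 ± 0.17 in control and -0.03 ± 0.30 in smoke (SD, n = 3), a difference of -1.64 (SE 0.271). For ASCRP3008172 the difference was -1.61 (SE 0.281). None of the 4 passed the correction for multiple tests (limma adjusted p = 0.565 for each). The probes are known here by these identifiers alone, with no circRNA name or host gene paired to them. Among the probes that met these 2 conditions, the 10 with the smallest p in each direction differed by 1.27 to 2.13 and by -1.77 to -1.13, with adjusted p between 0.565 and 0.820.

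No circRNA probe was called higher and none lower in smoke: 0 of the 13126 tested had a limma adjusted p under 0.05, and the smallest was 0.565. An unadjusted p under 0.05 was found for 651 probes (4.96%), against 656.3 if all p-values were evenly spread. Other groupings of the same arrays into 3 and 3 gave from 13 to 3767 such probes, so this match does not show that nothing differed. With the negative-probe mean as a covariate, a setting chosen after seeing the data, there were 1714. A per-probe test without shared variance estimates also called 0 probes, with 801 at an unadjusted p under 0.05. The groups did not overlap for 1460 probes (11.1%), where chance gives 10%. Most fold changes were small, with a median of 0.05 and 5th and 95th percentiles of -0.54 and 0.77 on the log2 scale. The median half-width of the 95% interval was 0.76. The interval lay within a 2-fold change in either direction for 44.5% of the probes and within a 4-fold change for 94.3%. At the looser criterion of a fold of at least 1.5 and an unadjusted p under 0.05, 530 probes were higher and 115 lower. The higher ones were somewhat dimmer than the tested probes as a whole, with a median level of -1.48 against -1.06. The lower ones were much brighter, with a median level of 1.34. The filter let 2301 of the 13126 probes through by the smoke arrays alone and 1 by the control arrays alone, and among probes well above background on all 6 arrays 412 were higher and 135 lower. These counts rested on single arrays: 175 were higher without smoke 1, 317 without control 2 and 839 without control 3, and 45 were lower without control 1, 53 without smoke 1, 74 without smoke 2 and 378 without smoke 3. Without scaling between arrays, which raises every difference by 0.376, the counts were 1135 higher and 9 lower, and with a background taken from the negative probes, a setting chosen after seeing the data, they were 379 and 180.

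**Figure D2:**
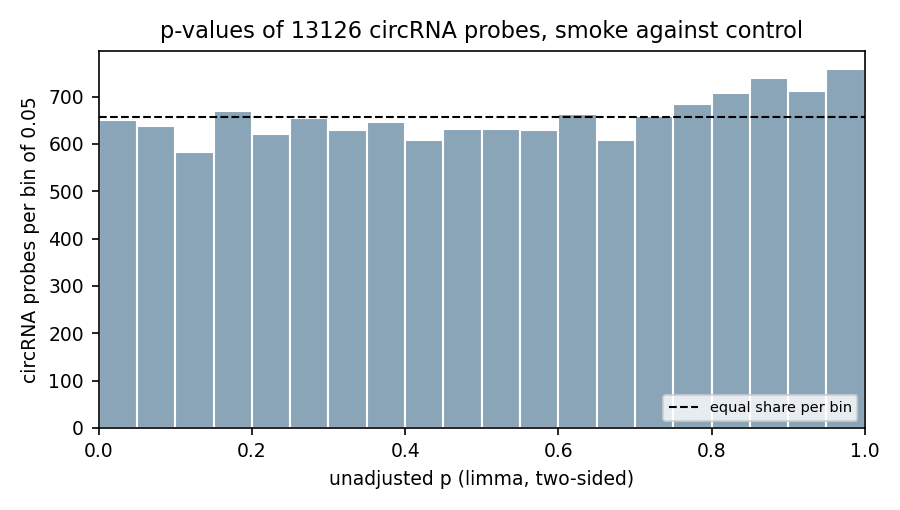
Number of circRNA probes (vertical axis) in each bin of 0.05 of the unadjusted limma p (horizontal axis) for smoke against control, with 13126 probes in all. The lowest bin held 651 probes, close to the equal share of 656.3 drawn as a dashed line, and the highest held 759.

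Since the RNA had been treated with RNase R, an mRNA probe measures what was left after it, not the mRNA level in the cells. Among the named mRNAs, the largest difference was that of MTDH, which encodes metadherin, a protein overexpressed in many tumours. Its signal was -2.50 ± 0.25 in control and -1.27 ± 0.46 in smoke (log2 relative to the 75th percentile, SD, n = 3), a difference of 1.23 (SE 0.363) or 2.35-fold, with all 3 smoke arrays above every control. PRIM1, the catalytic subunit of DNA primase, was 0.30 ± 0.17 in control and 0.95 ± 0.17 in smoke (SD, n = 3), a difference of 0.65 (SE 0.306) with no overlap. DYNLL1, a dynein light chain, differed by -0.33 (SE 0.303), and PIMREG, which is expressed in mitosis, by -0.29 (SE 0.298), again with no overlap of the groups. Neither these nor any other of the 64 mRNA probes tested passed, and 4 of 64 without overlap (6.25%) is fewer than the 10% that chance gives. The smallest limma adjusted p was 0.657, for MTDH, the only mRNA under 0.05 before adjustment. A per-probe test without shared variance estimates called 0. With the mean signal of the mRNA probes as a covariate, a setting chosen after seeing the data, 4 were called: MTDH (1.06, limma adjusted p = 0.034) and TCF7 (1.08, adjusted p = 0.041) higher, and EIF3D (-1.38, adjusted p = 0.0095), a subunit of translation initiation factor 3, and the ribosomal protein gene RPS18 (-0.95, adjusted p = 0.041) lower. Without the covariate the differences of EIF3D and RPS18 were -0.49 (SE 0.921) and -0.16 (SE 0.820). The covariate averages the same probes that are then tested, so these calls are not independent of it. With 6 arrays and a covariate, their p-values also rest largely on variance estimates shared between probes. Over all alternatives MTDH differed by 0.51, with normexp on the median signals, to 1.64 (adjusted p from 0.034 to 0.996) and TCF7 by 0.51 to 1.29 (adjusted p from 0.041 to 0.998).

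Values are given for 10 members of the gene lists fixed in advance, in 5 of the 15 lists, and none of the 10 was called, either over all mRNA probes or adjusted over the list alone. Of the T-cell genes, TCF7, a transcription factor of T-cell development, differed by 0.87 (SE 0.430; -1.47 ± 0.73 in control and -0.59 ± 0.20 in smoke, SD, n = 3), and ZAP70, a kinase of the T-cell receptor, by 0.17 (SE 0.421). The DNA repair genes had differences of 0.59 (SE 0.632) for SMC6, a subunit of a chromosome maintenance complex, 0.58 (SE 0.655) for BRCA1, which acts in homologous recombination, and 0.05 (SE 0.596) for the helicase gene WRN. Of the cell-cycle genes, CCNA2, which encodes cyclin A2, differed by 0.30 (SE 0.363), and CENPE, a kinetochore motor, by 0.07 (SE 0.621). The chromatin remodelling genes BAZ1A and SMARCAD1 differed by 0.25 (SE 0.410) and 0.22 (SE 0.507). The glycolytic gene PGK1 differed by 0.26 (SE 0.320). All 10 had a limma adjusted p of 0.992. SMC6, BRCA1, ZAP70, BAZ1A and SMARCAD1 were not well above background on every control array (the control mean of BRCA1 was -4.03), so the sizes of their differences are uncertain. Leaving out 1 array gave 0.03 to 1.13 for SMC6, 0.14 to 1.24 for BRCA1, -0.43 to 0.56 for WRN, 0.13 to 0.55 for CCNA2 and 0.01 to 0.58 for BAZ1A. It gave -0.46 to 0.63 for CENPE, -0.15 to 0.53 for ZAP70, -0.20 to 0.67 for SMARCAD1 and 0.13 to 0.41 for PGK1. The sizes of these differences thus varied with single arrays, and the sign turned for WRN, CENPE, ZAP70 and SMARCAD1 but not for the others. For TCF7 the range was 0.61 to 1.29. The sign of SMC6, BRCA1, WRN, CENPE, ZAP70, BAZ1A and SMARCAD1 turned with at least 1 background correction or scaling. The mean level of all 70 mRNA probes varied within both groups, with -2.51, -2.32 and -1.43 on controls 1, 2 and 3 and -1.80, -1.30 and -2.63 on smoke arrays 1, 2 and 3. The lists for aryl hydrocarbon receptor targets, the antioxidant response, the integrated stress response, p53 targets, inflammatory signalling, splicing factors, ubiquitin ligases and the markers of other cell types had 0 members among the mRNA probes. The 15 circRNA control probes, 12 lower and 3 higher, included 0 called (0 at an unadjusted p under 0.05; smallest limma adjusted p = 0.900).

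**Figure D3:**
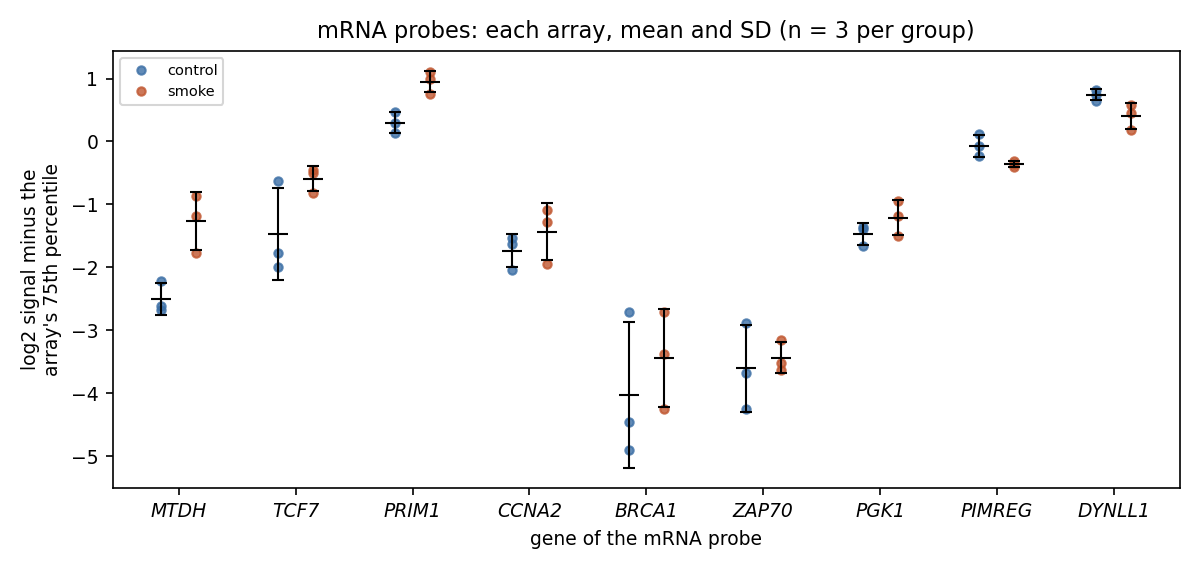
Log2 signal relative to the array's 75th percentile for 9 named mRNA probes, with 1 point per array (blue, control; orange, smoke) and the mean with its SD as a bar (n = 3 per group). The points of MTDH and PRIM1 lay higher in smoke than in control, and those of DYNLL1 and PIMREG lower, with no overlap, and none of the 9 passed the adjusted threshold.

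Arrays of the same group were no more alike than arrays of different groups. The correlation of circRNA levels across 13104 probes, which are not independent replicates, averaged 0.923 within groups and 0.926 between groups. The closest arrays were control 1 and smoke 3 (r = 0.970), and the most distant were control 3 and smoke 3 (r = 0.858). The first 3 principal components held 54.5%, 20.3% and 16.4% of the variance. Exposure accounted for 17.5% of the variance, where a random grouping of the 6 arrays gives 20% on average.

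**Figure D4:**
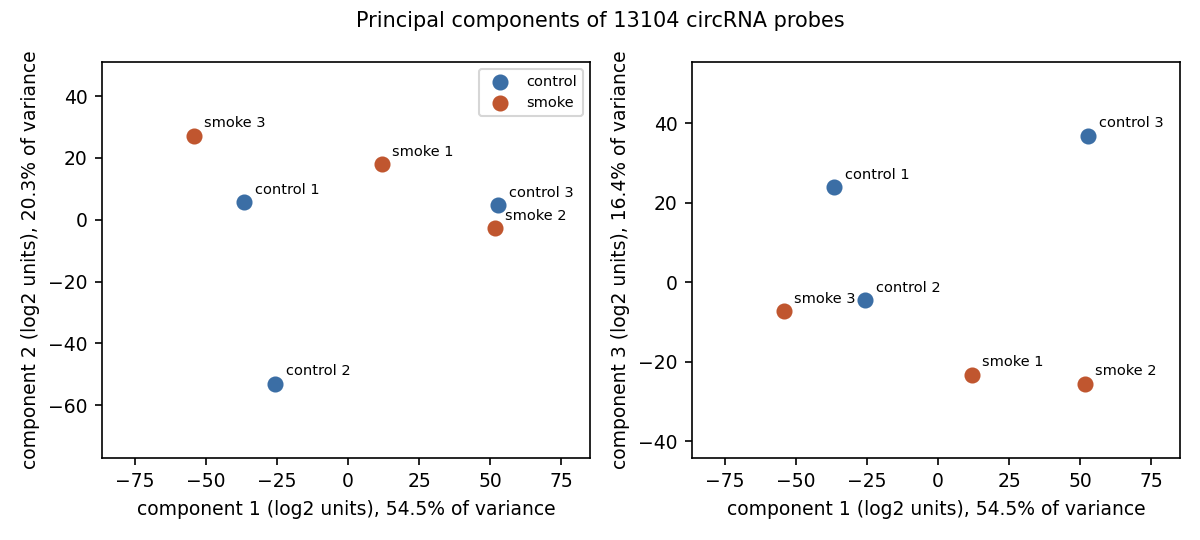
Principal component scores of the 6 arrays over 13104 circRNA probes (log2 units), with component 1 on the horizontal axes and component 2 (left) or 3 (right) on the vertical axes; blue is control and orange is smoke. On component 1, control 3 (52.9) and smoke 2 (51.7) lay at one end and smoke 3 (-54.3) and control 1 (-36.5) at the other.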

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

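The settings with the negative probes, the mRNA mean, the array row, or without control 3 and smoke 2 were chosen after seeing the data. Under all 28 alternatives, 0 circRNA probes were called in either direction (smallest limma adjusted p from 0.140 to 1.000). Of the 27 run on the mRNA probes, the mRNA mean as a covariate, which includes the tested probes, gave 4 calls and the others 0. With these arrays the spread limits what can be called: in simulated data 3.2% of 2-fold and 72.3% of 4-fold changes were recovered. The simulated probes were independent, whereas the first component of the real arrays held 54.5% of the variance, so these rates may not hold for them. Dim probes are limited further by the negative probes, of which 8 to 54 of 60 were marked well above background. ASCRP3009687, ASCRP3012600, ASCRP3007235 and ASCRP3008172 had the same direction under all 24 alternatives run on them, as did MTDH, PRIM1, TCF7, CCNA2 and PGK1 under 23. Many of these outcomes were fixed in advance. The circRNA probes, MTDH and PRIM1 were picked for no overlap between groups, so leaving out arrays could not turn their sign. The filter, the replicate block and the variance model leave the difference of any probe as it was.

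The looser count of 530 higher and 115 lower circRNA probes (fold of at least 1.5, unadjusted p under 0.05) moved most. Beyond the values given here, the cause was not tested. It was 1135 higher and 9 lower without scaling, where the median of all circRNA probes shifted to 0.42 from 0.05. It was 221 higher and 102 lower with normexp on the median signals, and 180 lower with a background from the negative probes. An unadjusted p under 0.05 alone was met by 674 probes with normexp, against 651 in the main fit. The smaller count with normexp thus arose at the fold criterion, not at the p. It became 866 and 560 with the negative-probe mean as a covariate, 835 and 708 with the mRNA mean, and 293 and 49 with the array row, assumed from a header field, as a block. Row 1 alone, with 1 smoke array assumed to vary like the controls, gave 297 higher; row 2 holds smoke arrays only. Without control 3 and smoke 2, 48 were lower. Leaving out each array in turn gave 175 (without smoke 1) to 839 (without control 3) higher and 45 (without control 1) to 378 (without smoke 3) lower; without control 2, 317 were higher, and without smoke 2, 74 lower. Of the 645 probes, 455 were shared with quantile normalisation, 353 with the authors' deposited values and 410 with the background from the negative probes.

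The replicate numbers showed no sign of pairing the flasks: deviations from the group means correlated at -0.111, -0.049 and -0.639 for numbers 1, 2 and 3, and 0 of 6 arrays correlated best with their own number. With the replicate block, 335 circRNA probes were higher and 62 lower, and 0 were called.

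Of 406 values of the 18 named probes under the alternatives, 37 changed sign and 2 became calls. The 406 include differences under another filter, the replicate block or another variance model, which equal the main ones and could not change sign. All 37 belong to mRNA differences that were not called. Of these, 3 follow from a shift of all probes alike: leaving out the scaling adds 0.376 to every difference (DYNLL1 0.043, PIMREG 0.081), and median scaling adds -0.067 (WRN -0.021). The cause of the other 34 was not tested. Quantile normalisation gave -0.032 for WRN and -0.22 for ZAP70. Normexp on the median signals gave -0.079 for SMC6, -0.16 for BRCA1, -0.078 for WRN, -0.010 for CENPE, -0.23 for ZAP70, -0.10 for BAZ1A and -0.12 for SMARCAD1. The background from the negative probes gave -0.081 for SMC6, -0.14 for BRCA1, -0.0091 for WRN, -0.19 for ZAP70, -0.086 for BAZ1A and -0.12 for SMARCAD1. The negative-probe covariate gave -0.37 for WRN, -0.35 for CENPE, -0.030 for ZAP70 and -0.10 for SMARCAD1. The mRNA-mean covariate gave -0.028 for BRCA1, -0.47 for WRN, -0.44 for CENPE, -0.11 for ZAP70, -0.029 for BAZ1A and -0.18 for SMARCAD1. Without control 3 and smoke 2, WRN was -0.016 and CENPE -0.10. Leaving out 1 array gave -0.43 to 0.56 for WRN, -0.46 to 0.63 for CENPE, -0.15 to 0.53 for ZAP70 and -0.20 to 0.67 for SMARCAD1, and, without a change of sign, 0.032 to 1.1 for SMC6, 0.14 to 1.2 for BRCA1, 0.010 to 0.58 for BAZ1A, 0.13 to 0.55 for CCNA2, 0.13 to 0.41 for PGK1 and 0.61 to 1.3 for TCF7. Array quality weights did not converge (63.2 for smoke 1 against 0.273 to 0.971 for the other arrays) and were not run, and a slide block was not run because all arrays share 1 slide.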

Other observations

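Planned here were the counts of calls under other splits and the looser counts under other scalings, without 1 array or for probes well above background on all 6 arrays; the background correction from the negative probes was added after the data were seen, though before its own results, and the other tests were chosen only after the results were seen. Several mRNA probes for abundant housekeeping genes, also picked after their values were seen, varied far more between arrays of 1 group than between groups. EIF3D, a translation initiation factor subunit, was at -2.32, -2.74 and 0.68 on controls 1, 2 and 3 and at -1.68, -1.20 and -2.98 on smoke arrays 1, 2 and 3. The ribosomal protein genes RPS18, RPLP1 and RPL10 were at 1.45, 0.59 and -0.74 on control 3 but at -1.42, -1.70 and -2.25 on control 2, and the histone gene H3-3A was at 1.00 and -0.49. The difference of EIF3D between groups was -0.49 (SE 0.921), and those of the other 4 were -0.16 (SE 0.820), -0.04 (SE 0.762), -0.05 (SE 0.668) and 0.02 (SE 0.772). GAPDH, a glycolytic enzyme, varied less, from 0.62 to 1.33, with a difference of -0.05 (SE 0.343). PFN1, which encodes the actin-binding protein profilin 1, was at 3.38 on both smoke 1 and smoke 2 and at 5.32 on smoke 3, against 4.26 to 5.17 in control. CD69, a marker of early T-cell activation, was well above background on 1 control and 2 smoke arrays and was not tested (-4.98 ± 1.35 and -4.73 ± 1.61, SD, n = 3).

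Of 9 tested mRNA probes for DNA replication and S-phase genes, 8 were higher in smoke, with a median difference of 0.58 against 0.05 for the other mRNA probes, and 0 of 9 were called; ATAD2 and BRCA1 were not well above background on every control array, and over the other 7 the median was 0.36. PRIM1 had 0.65 (SE 0.306), CHAF1B, a chromatin assembly factor, 0.72 (SE 0.436), the exonuclease gene EXO1 0.59 (SE 0.394) and ATAD2 0.94 (SE 0.844), and WDHD1 had -0.33 (SE 0.546); with the mean of the mRNA probes as a covariate 5 of 9 were higher with a median of 0.15, where PRIM1 (0.75) and WDHD1 (-0.74) lay further from 0 and CHAF1B (0.41), EXO1 (0.31) and ATAD2 (0.18) nearer. Of all 64 tested mRNA probes, 40 were higher in smoke. A candidate explanation is a rise in signal of the replication probes relative to the other mRNA probes. Camera with a preset correlation gave p = 0.0119 and with an estimated correlation of 0.497 among the members p = 0.271, so it stays open. After RNase R, the mRNA levels in the cells cannot be read from these probes. Of 6 probes for mitosis and kinetochore genes, 2 were higher and 4 lower (median -0.09; KIF20A -0.15, ITGB3BP -0.17; with that covariate 0 of 6 higher, median -0.28), and camera gave p = 0.105 with the preset and p = 0.392 with an estimated correlation. Both lists were written from textbook functions after the values were seen.

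The arrays differed mainly along an axis other than exposure: of the 10 splits of the 6 arrays, the one with control 1, control 2 and smoke 3 on one side and control 3, smoke 1 and smoke 2 on the other called 1146 circRNA and 39 mRNA probes, which points to a structure of the samples or of the arrays. Additive non-specific signal stays open as its cause. After a background correction from the negative probes the first component held 52.3% of the variance (54.5% before). Its axis was nearly the same (r = 0.953 between the scores of the 6 arrays). That share cannot decide the question, because the correction lowered the component's own variance and the total together. They fell from 0.134 to 0.081 and from 0.246 to 0.155 (log2 units squared). In this split the correction left 0 calls and 1927 of 3647 probes at the looser criterion. It lowered the split's share of the variance from 48.8% to 38.4%. The negative-probe mean as a covariate, itself close to the component (r = 0.968, n = 6 arrays), left 0 calls and 104 probes. Linear RNA left after RNase R may contribute, as the mRNA probes rose along the component more steeply than circRNA probes of like level. The median difference was 0.295 log2 units per SD (95% bootstrap interval 0.155 to 0.392). However, 51 of 60 negative probes rose as well (median slope 0.495 against 0.544 for the mRNA probes). They rose less steeply than circRNA probes of their level (-0.176, interval -0.299 to -0.048). Both intervals take probes as independent, although every slope rests on the same 6 arrays. The brightest mRNA probes were nearly flat or went the other way (PFN1 -0.33, POLR2A -0.27, ACTG1 -0.03, GAPDH 0.16). The steepest were dim and not tested (POGLUT2 1.48, CD69 1.31), though the brighter RPS18 was steep too (1.08). Exchanged labels of control 3 and smoke 3 cannot be told apart from such a structure of the samples or of the arrays. The reason is that 0 mRNA probes measure a gene of the aryl hydrocarbon receptor or antioxidant lists. Before scaling, control spots of the classes DCP, E, eQC and ETG were brighter on control 3 and smoke 2 than on control 1, control 2 and smoke 3. For eQC the means were 5.97 and 5.17 against 3.93, 3.48 and 3.69 (log2). The classes DarkCorner, GE and RC did not follow this order. These means include the brightness of each array as a whole, so they cannot place the axis in the samples or on the arrays. Its origin was not tested, nor was a biological explanation of it.

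At the looser criterion, circRNA probes higher in smoke outnumbered lower ones by 4.61 to 1, a ratio that ran from 1.52 (without smoke 3) to 9.69 (without control 1) when 1 array was left out. Scaling between arrays stays open: the ratio was 3.73 under quantile normalisation (0.923 to 6.39 leaving out 1 array), 2.65 under median scaling and 126 with none, where the last 2 shift every difference alike, by -0.067 and 0.376. Additive signal raising dim probes stays open: with a background from the negative probes the ratio was 2.11, with a 95% counting interval of 1.76 to 2.51 that takes probes as independent and includes the bound of 2, and ran from 0.642 to 2.63 leaving out 1 array, while it was 3.05 among probes well above background on all 6 arrays and 2.72 among those above the 95th percentile of the negative probes throughout at least 1 group. A structure of the arrays unrelated to exposure stays open. Of the other splits, 2 were as uneven, at 72 to 1 and 7.55 to 1, but over 219 and 94 probes. The real split had 645 probes at this criterion. The other splits with at least as many, 3647, 809 and 2138, had lower ratios of 3.98, 3.09 and 2.49. An effect of smoke on dim circRNAs stays open as well and was not tested separately.

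For the comparison of smoke with control, the 10 possible splits are too few for a share under 0.05. The real count of called circRNA probes was 0, which every split must equal or exceed, so that count decides nothing, and the highest other count was 1146. As many circRNA probes at the looser criterion as the real 645 were found in 4 splits, the real one included, and the highest other count was 3647. The same holds for the real count of 0 called mRNA probes, with 39 as the highest other count.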
